A study of Litchi chinensis with 12 samples.

How the data were processed

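Small RNA and RNA ends were measured in litchi (Litchi chinensis), an evergreen fruit tree. Small RNA libraries came from pedicel, flower, fruitlet, leaf, root and stem. Parallel analysis of RNA ends (PARE) captures the 5′ ends of uncapped transcripts and so reads where a microRNA has sliced its target. PARE libraries came from fruitlet, pedicel, flower and a mix of equal RNA amounts of the 6 tissues. Per the labels' protocols, the tissues were taken from 'Huaizhi' trees in an orchard, sets of 3 trees counted as biological replicates, and total RNA was extracted with Trizol and Fruit-mate before standard Illumina library preparation. Strand-specific RNA-seq of flower was not analysed here. No tissue had more than 1 small RNA and 1 PARE library, and leaf, root and stem had no PARE library of their own, so no tissue difference could be tested against biological replicates.

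The deposited tables hold raw read counts, 1 line per distinct sequence and its count, with no normalization by the authors that the values show. Small RNA tags were 18 to 34 nt long. PARE tags of the mix were 18 to 34 nt long, with 65.1% of reads at 20 nt, whereas all tags of the other 3 PARE libraries were 47 nt long, so the mix was prepared or trimmed differently. The submitters' processing notes name Bowtie 1.0 and STAR, the latter without a version, and do not say what each was used for. Adapter trimming, quality filters and the genome build are not given in the sources used here. No reference genome was used here, so no position in the genome and no gene name is given for a target, and the phased locus search planned for a genome was not run.

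Levels are reads per 1000000 reads of the library (RPM), computed from the deposited counts. A tag of 20 to 22 nt was assigned to 1 of 35 listed families when its first 20 nt differed by at most 2 substitutions from a listed sequence, aligned at the 5′ end; the nearest family won. The families belonged to the lists development, auxin, nutrient, silencing machinery, phasiRNA trigger (microRNAs known to start phased siRNAs) and tasiRNA, and 1 further family. A family was called enriched when its highest tissue lay at least 4-fold above the median of the other 5 tissues with at least 10 RPM, and depleted when its lowest tissue lay at least 4-fold below the median of the others with that median at least 10 RPM. The text names the 10 families with the highest mean level, every enriched or depleted family, the families of the trigger, machinery and tasiRNA lists that reached 10 RPM, the most abundant tag of each tissue and of the named families, the families with a PARE signature, and the leading PARE tag of the 8 families with most reads at the slice position. Those rules, the lists and the alternatives in the closing section that are not called added were chosen before the data were examined. Marker lists of other organisms and of structural RNAs (5.8S rRNA, tRNA-Ala and tRNA-Gly) were counted by sequence, and a longer list of 8 arthropod and 7 vertebrate microRNAs was added later.

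For double-stranded precursors, the share of distinct tags of 21, 22 and 24 nt with at least 2 reads whose partner on the other strand would leave 2-nt 3′ overhangs was counted and set beside overhangs of 3 to 10 nt, with tags of listed families left out. The planned PARE signature counted tags that start with the reverse complement of nts 1 to 10 of a family sequence (at most 1 mismatch, nt 1 free). It required more than 10 reads, 4 times the highest count at 10 other tag positions, and more reads than 95 of 100 shuffled sequences. Relations over the 6 tissues were tested with Pearson's r and Spearman's rho by exact two-sided permutation over 720 pairings, with Benjamini-Hochberg adjustment over the 2 planned relations.

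After the data had been seen, full target sites were searched as well. Each of 45 abundant family tags of 31 families was aligned within each of the 16784599 distinct 47-nt PARE tags. A site that no single tag spanned could not be found. Tags were joined only afterwards, to count read starts around a site. A G:U pair cost 0.5 and a mismatch 1, doubled at nts 2 to 13 of the small RNA, with a score of at most 4. A site was called when a library had at least 10 reads that start between the pairs of nts 10 and 11, and at least 4 times the reads of any other start in the window; 5 shuffled sets of the same tags were the background. Sequence downstream of a called site was extended through overlapping PARE tags to at most 400 nt. With at least 105 nt and 50 siRNA reads of 21 nt, the reads were sorted into the 21 possible registers, on both strands, and the register starting at the slice was compared with the other 20. PARE starts followed by siRNAs in register were counted as well, beside 5 shifted registers.

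Base forms were compared because slices differed between libraries, again after the data had been seen. PARE tags of 47 nt with at least 2 reads that were equal except at 1 base, for 9 bases along the tag, were grouped. A base had opposite forms in a pair of libraries when each had at least 20 reads and a form made up at least 95% of the reads in one and at most 5% in the other. Each base was counted once by the 15 nt around it. Sequences of 20 to 24 nt that hold such a base were then counted in the small RNA libraries and the PARE mix, with at least 5 reads per base.

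Total counts were 18881200 to 20874962 reads per small RNA library and 19625227 to 23067389 per PARE library. Intervals are exact 95% intervals, Clopper-Pearson for shares and Poisson for levels. They cover counting error only, since reads copied by PCR are not independent molecules, and a count of 0 allows up to 3 reads. Alternatives changed the scaling (reads of 20 to 24 nt, family reads, median of ratios), the match, the fold and read minimums, the length window, singletons and depth. Each statistic was tested on simulated data. All 1400 planted family tags were assigned and none of 100000 random tags, 100 of 100 families raised 8-fold were called and 0 of 600 unchanged ones. The planned signature called 4 of 5 planted families, the site search 20 of 20 planted slices and 0 of 20 sites without one, the register count 20 of 20 loci, and the base comparison 60 of 60 planted bases and 0 of 300 others. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0, numba 0.67.0 and matplotlib 3.10.9.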

Results

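Small RNA libraries of 6 litchi tissues and PARE libraries of 3 of these tissues and of their mix were compared to ask which microRNAs and siRNAs each tissue held and which transcripts they sliced. The title of the series names phased siRNAs (phasiRNAs), secondary 21-nt siRNAs made in steps from a transcript that a microRNA has sliced, and alternative splicing, which was not analysed here. Depth was even among the small RNA libraries, at 19708997 reads in pedicel, 20246261 in flower, 18881200 in fruitlet, 20874962 in leaf, 20084539 in root and 18907665 in stem. PARE libraries had 19625227 reads in the mix, 23067389 in fruitlet, 21143654 in pedicel and 23066895 in flower. With 1 library per tissue there are no replicates, so differences between tissues describe these libraries, and intervals cover counting error only.

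The 24-nt class, the size of siRNAs that direct DNA methylation in plants, was the largest in all 6 tissues. It made up 59.0% of the 20 to 24 nt reads in flower, 56.4% in leaf, 54.4% in stem, 45.1% in fruitlet, 43.8% in root and 39.9% in pedicel. The 21-nt class, the usual size of microRNAs and phasiRNAs, took 29.2% in pedicel, 24.1% in fruitlet, 20.3% in root, 19.5% in leaf, 18.8% in flower and 17.4% in stem. No exact binomial interval was wider than 0.0458 percentage points. Among 24-nt reads, 53.6% (root) to 66.7% (leaf) began with A, and among 21-nt reads 45.98% (pedicel) to 63.5% (leaf) began with U. When each sequence was counted once, root replaced pedicel as the tissue with the largest 21-nt share, at 10.4% against 5.93% in flower, and as that with the smallest 24-nt share, at 54.8% against 74.3% in flower. Fragments of structural RNAs were highest in pedicel and root. tRNA-Ala fragments reached 0.802% of reads in pedicel and 0.699% in root, with 0.396% in stem and 0.130% to 0.184% in the others. Fragments of 5.8S rRNA reached 0.461% in root and 0.334% in pedicel, and tRNA-Gly fragments stayed at 0.00124% to 0.00424%.

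**Figure D1:**
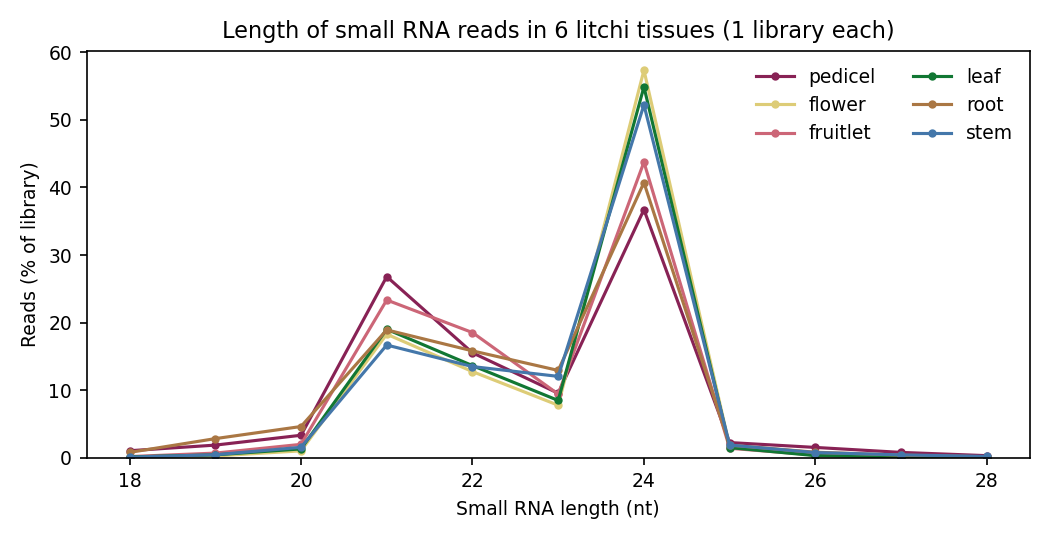
Percent of reads (y axis) at each small RNA length in nt (x axis) in 6 tissues, 1 line per library. All lines peak at 24 nt, and flower, with 59.0% of its 20 to 24 nt reads in that class, lies above pedicel, with 39.9%.

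The most abundant family was miR165/miR166, which targets the leaf polarity genes of the HD-ZIP III class, at a mean of 20132 reads per 1000000 reads (RPM) and from 10139 in fruitlet to 34515 in leaf. miR167 followed with 3654, miR156/miR157 with 3020 and miR168, which targets the slicer gene AGO1, with 1920 RPM. Next came miR164 (988 RPM), miR172 (758), miR482/miR2118 (413), miR535 (319), miR159 (176) and miR390 (169). A single miR165/miR166 sequence, TCGGACCAGGCTTCATTCCCC, was the leading tag of pedicel, flower and stem, at 16224, 15292 and 18962 RPM. In leaf and root the leading tag was the 22-nt TTGGACAGAAAAATCACGGTCA, at 25857 and 14171 RPM. It equals the leading miR3954 tag with 1 extra nt at the 5′ end, so the planned match, which aligns 5′ ends, left it out. With a shift of 1 nt allowed, an alternative added after the data were seen, miR3954 rose from 11.2 to 58.6 RPM over the tissues to between 4496 (pedicel) and 27509 (leaf). The fruitlet library was led by the 21-nt GAAGAAGACTGCCATAACTGA at 8589 RPM, which belongs to no listed family. No read was assigned to miR529, miR2950 or miR4376, which allows up to 3 reads in each library.

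Of the 9 families enriched in a tissue, 7 were regulators of development. In that list, 7 of 12 families with reads were enriched in a tissue, 4 were depleted in a tissue and 5 were neither. miR172, which represses AP2-type flowering genes, was 6.27-fold enriched in leaf, at 2671 RPM (95% Poisson interval 2649 to 2693), and 8.14-fold depleted in flower, at 63.1 (59.7 to 66.7). The leaf enrichment fell to 3.27-fold when levels were scaled to family reads and was 18.6-fold without pedicel and root. miR156/miR157, which keeps plants juvenile by repressing SPL genes, was 5.76-fold enriched in flower (8048 RPM) and 7.34-fold depleted in fruitlet (430), but with scaling to family reads the flower enrichment was 3.77-fold and neither call held. miR164, a repressor of NAC boundary genes, was 14.9-fold enriched in root at 4291 RPM against a median of 289. miR319, which targets TCP genes of leaf growth, was 17.8-fold enriched in stem at 63.8 against 3.58, 41.1-fold with exact matches, 10.8-fold with at most 3 substitutions and 28.01-fold without pedicel and root. miR394 was 9.20-fold enriched in root (102 RPM) and 8.04-fold depleted in fruitlet (1.43, from 27 reads). The fruitlet call was lost with scaling to family reads and with a minimum of 50 RPM. miR535 was 4.95-fold enriched in leaf at 1017 RPM, 3.17-fold with median-of-ratios scaling and 13.9-fold without pedicel and root. miR169 was 4.28-fold enriched in flower (61.2 RPM) and 8.37-fold depleted in root (4.03), but with either of these scalings its highest tissue was fruitlet. Its flower call was also lost with a 5′ shift of 1 nt, and its root call with a minimum of 50 RPM.

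In the auxin list, 1 of 3 families was called. miR167, which targets auxin response factors, was 6.67-fold enriched in flower at 8801 RPM (8760 to 8842) and 17.3-fold depleted in pedicel at 293 (286 to 301), and with scaling to family reads its highest tissue was fruitlet. Exact matches lost both calls, with pedicel 1.59-fold under the median, and without pedicel and root the flower value was 1.73-fold. In the nutrient list, 1 of 7 families was enriched, miR398 in stem at 15.97 RPM, 4.58-fold over the median, a call lost with exact matches and with a minimum of 50 RPM. The copper-related miR397 and miR408 were 8.41-fold and 16.4-fold depleted in fruitlet, at 2.44 RPM each (1.78 to 3.25), and these calls were lost with that minimum too. None of the 3 families against genes of silencing itself was called. miR168 ranged from 1046 RPM in fruitlet to 2655 in pedicel, miR162, which targets the dicer gene DCL1, from 58.1 in stem to 115 in leaf, and miR403, which targets AGO2, from 12.1 in stem to 78.6 in leaf.

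Among the 6 phasiRNA trigger families with reads, none was enriched and 2 were depleted. miR482/miR2118, known to slice transcripts of NBS-LRR disease resistance genes, was 5.63-fold depleted in fruitlet at 75.6 RPM (71.8 to 79.7) against a median of 426, a call lost with scaling to family reads, with exact matches and with at most 1 substitution. miR390, the trigger of TAS3 tasiRNAs, was 8.37-fold depleted in root at 23.5 RPM (21.4 to 25.7). The tasiARF siRNAs made from TAS3, which target auxin response factors, were 9.51-fold depleted in the same tissue, at 9.51 RPM against a median of 90.4, a call lost with exact matches, which found almost no reads. miR858 averaged 19.2 RPM, miR3954 31.5 and miR7122 16.9; the leading miR7122 tag TTAGACAGAAAAATCACGGTCA (825 reads) differed by 1 substitution from the leading tag of leaf and root. The next miR7122 tags, with 603 and 428 reads, also differed from it by 1 substitution each. The miR7122 level was highest in leaf (31.4 RPM) and lowest in pedicel (6.04), as was that of the abundant tag (25857 and 4171). Whether miR7122 reads are variants of that tag was not tested, so the miR7122 level and 22-nt share may not be those of a separate family. miR828, a trigger of TAS4, reached at most 1.34 RPM, in leaf (0.891 to 1.94). The 22-nt form, linked with phasiRNA production, made up 99.5% of miR482/miR2118 reads, 97.4% of miR7122, 85.0% of miR167 and 65.4% of miR828 (54.0% to 75.7%), 13.6% of miR858, 1.11% of miR3954 and 0.476% of miR390. With the 5′ shift the miR3954 value turned, since its 22-nt tag had 1520092 reads, 93.8% of those in the widest match of the family.

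In all, 9 families were enriched and 10 depleted. Levels moved with the scaling. Listed families took 1.94% of reads in fruitlet and 5.12% in leaf, and miR165/miR166 alone took 45.5% to 78.2% of these. Relative to RPM, median-of-ratios scaling shifted log2 levels by 0.47 in fruitlet, 0.27 in stem and -0.61 in leaf, and scaling to family reads by 0.65 in fruitlet, 0.25 in root, 0.19 in pedicel, 0.13 in stem, -0.48 in flower and -0.75 in leaf. Only 4 of the 9 enriched and 7 of the 10 depleted calls were kept with scaling to family reads, and 7 and 10 with median-of-ratios scaling. Without pedicel and root, the libraries with most structural RNA, 6 of each kind were kept. Without flower, whose reads carried other base forms as described later, 6 enriched and 9 depleted calls were kept. A call made in a left-out library cannot be kept. All calls lost without flower were flower calls. Those lost without pedicel and root were pedicel or root calls, except the flower enrichment of miR167. The leading tags of the families called were TTGACAGAAGATAGAGAGCAC for miR156/miR157 (247396 reads over the libraries), TGAAGCTGCCAGCATGATCTTA for miR167 (285227), TGGAGAAGCAGGGCACGTGCA for miR164 (111870), AGAATCTTGATGATGCTGCAT for miR172 (89978), TTGCCAATTCCACCCATGCCGT for miR482/miR2118 (49123), TGACAACGAGAGAGAGCACGC for miR535 (37952), AAGCTCAGGAGGGATAGCGCC for miR390 (19511) and TTCTTGACCTTGTAAGACCCT for tasiARF (4430). For tasiARF, as for miR3954, the planned match left out more abundant tags, TCTTGACCTTGTAAGACCCTG (19866 reads) and TCTTGACCTTGTAAGACCTTT (19553), and with a 5′ shift of 1 nt its level ran from 60.7 RPM in root to 829 in leaf. Those of the rarer families were ATGCACTGCCTCTTCCCTGGC for miR408 (3446 reads), CAGCCAAGGATGACTTGCCGG for miR169 (3138), TTGGCATTCTGTCCACCTCC for miR394 (2768), TCATTGAGTGCAGCGTTGATG for miR397 (1188), TTGGACTGAAGGGAGCTCCCT for miR319 (861) and TGTGTTCTCAGGTCGCCCCTG for miR398 (847). Outside the calls, TCGCTTGGTGCAGGTCGGGAA led miR168 (196838 reads), TTTGGATTGAAGGGAGCTCTA miR159 (17770), TCGATAAACCTCTGCATCCAG miR162 (9607), TTAGATTCACGCACAAACTCG miR403 (4081), TGGACAGAAAAATCACGGTCA miR3954 (3167) and TTCGTTGTCTGTTCGACCTTG miR858 (1919).

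**Figure D2:**
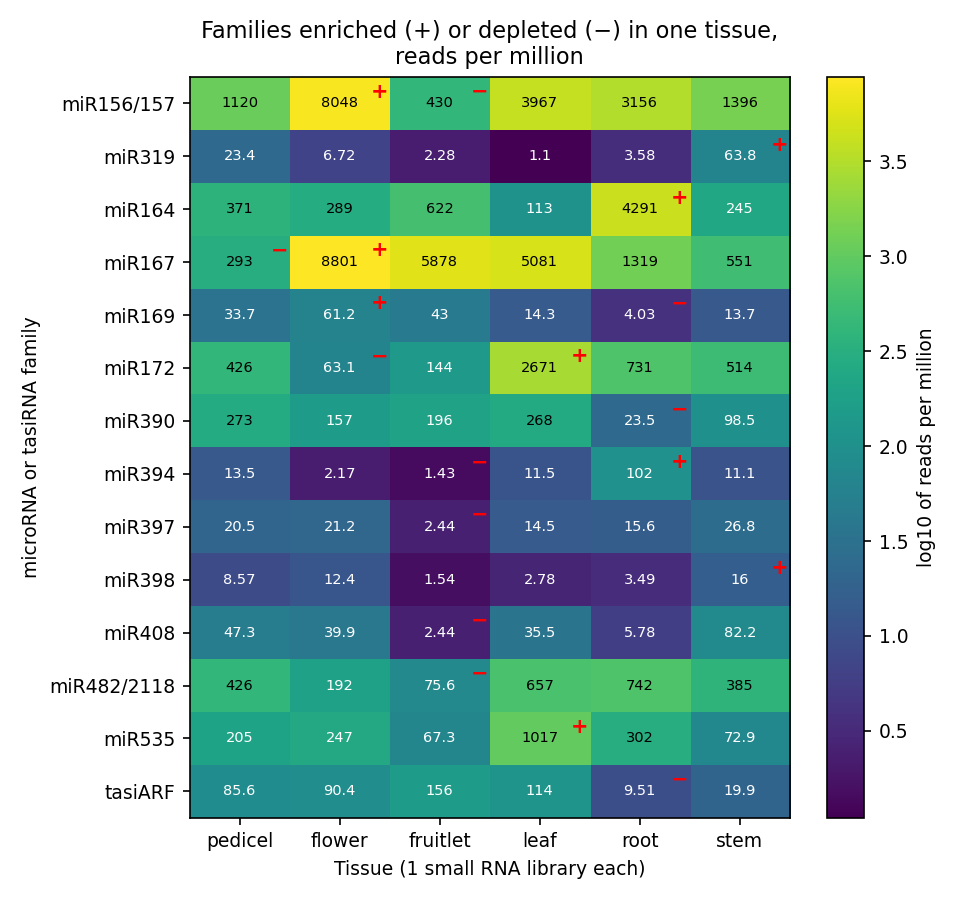
Levels in RPM (numbers; color gives log10) of the 14 families (y axis) called enriched (+) or depleted (−) in one of 6 tissues (x axis), 1 library each. miR164 stands out in root at 4291 RPM and miR172 in leaf at 2671; calls marked for miR156/miR157, miR167, miR169, miR172, miR394, miR482/miR2118 and miR535 changed with another scaling.

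Dicer products leave pairs of strands with 2-nt 3′ overhangs. Of the distinct 21-nt tags, 18.3% had such a partner in pedicel, 15.01% in flower, 18.8% in fruitlet, 14.0% in leaf, 12.1% in root and 14.2% in stem. These shares lay below the mean of the 3 to 10 nt overhangs, which ran from 13.1% in root to 20.01% in fruitlet, but the direction depended on the read minimum. A wider overhang leaves fewer nt to pair, so partners by chance are easier and this planned background can be raised by the count itself. With singletons, for example, the root share rose from 6.82% at 2 nt to 28.2% at 10 nt. A share below the background therefore does not speak against duplexes. By that planned background, 1 of 18 library and length pairs stood above it, 24-nt tags of root at 3.20% against 2.84%, whereas among tags with at least 10 reads 16 of 18 did. Against the nearest overhangs of 0, 1, 3 and 4 nt, a background added after the data were seen, the 2-nt share was higher in 18 of 18 pairs, by 1.03 to 1.08 times at 21 nt, 1.11 to 1.14 at 22 nt and 1.10 to 1.44 at 24 nt. It exceeded each of these 4 overhangs in 4 of 6 libraries at 21 nt, 5 at 22 nt and 6 at 24 nt, and with singletons in 0, 0 and 5.

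Levels of miR390 and tasiARF over the 6 tissues had Pearson r = 0.747 (exact permutation p = 0.0833, adjusted over the 2 relations 0.0958) and Spearman rho = 0.60 (exact permutation p = 0.242, adjusted 0.242), so the relation did not pass the test. Without root and pedicel r was 0.730. With a 5′ shift of 1 nt, which takes in the abundant tasiARF tags, r was 0.791 (exact permutation p = 0.0597, adjusted 0.0958) and rho 0.829 (exact permutation p = 0.0583, adjusted 0.0583), and 0.941 without root and pedicel. With median-of-ratios scaling r was 0.785 (exact permutation p = 0.0319, adjusted 0.0639) and rho 0.886 (exact permutation p = 0.0333, adjusted 0.0667), and with exact matches, which found almost no tasiARF reads, r was 0.210. For miR482/miR2118 against the 21-nt duplex share, r was -0.716 (exact permutation p = 0.0958, adjusted 0.0958) and rho -0.829 (exact permutation p = 0.0583, adjusted 0.117), which did not pass either. Without root and fruitlet r was -0.156, so this relation rested on those tissues. With the duplex excess over the overhangs of 0, 1, 3 and 4 nt the direction turned, to r = 0.510 (exact permutation p = 0.292, adjusted 0.292) and rho = 0.771 (exact permutation p = 0.103, adjusted 0.206). Flower differed from the rest in base forms, and the other 5 libraries fall below the minimum of 6 samples set for a correlation.

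PARE tags showed slices by microRNAs in every library when the full target site was read, a search added after the data were seen. In total, 140 sites of 21 families were called, 96 in the mix, 98 in fruitlet, 95 in pedicel and 106 in flower, while 5 shuffled sets gave 0 called sites from 42 to 82 candidate sites each, against 469 candidates for the real tags. Sites were counted by the sequence just downstream of the slice. Near-identical variants of a transcript can therefore count apart, and the totals are not numbers of loci or targets. miR482/miR2118 had 82 of the sites, 77 of them with the tag TCTTTCCAACACCTCCCATACC (15428 reads), which the planned family match left out, followed by miR3954 with 8, miR828 with 7, miR858, known to target MYB genes, with 6 and miR172 with 5. miR159, miR169 and miR319 had 4 each. Reads at miR482/miR2118 slices summed to 4265 RPM in flower, 3445 in fruitlet and 916 in pedicel, and to 1058 in the mix. Slices by miR390 ranged from 67.3 RPM in flower to 258 in fruitlet, and those by miR319 from 72.8 in pedicel to 343 in flower. The mix, with its shorter tags, cannot be compared with the others in level, and its miR160 and miR396 slices stood at 410 and 228 RPM. At the miR160 site AGGCATACAGGGAGCCAGGCA, the slice start had 8027 reads in the mix, 1007 in fruitlet, 207 in pedicel and 1590 in flower, against at most 52, 10, 3 and 19 at any other start. At the miR828 site GGAACACTCATTTGAGCAAGA, the start TTGAGCAAGATGTAATGAGC had 2530, 5726, 5346 and 7798 reads in the same order. These examples were chosen after their values were seen.

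The planned signature, which uses only the first 10 nt of the family, called 4 families. These were miR160 in the mix, with 9235 reads at the slice position and 7.89 times the highest other position, miR7122 in the mix (4.04 times), miR828 in fruitlet (4.03 times) and miR319 in flower (4.66 times). Pedicel had 0 families. The count was 8 with no mismatch allowed and 0 when each tag was counted once. The leading tags at that position began with ATTGGAAAGAAAAAATAGAC for miR482/miR2118 (22213 reads), TTGAGCAAGATGTAATGAGC for miR828 (21396), AGACAACGAAATAAAGAATT for miR858 (11255), AGCTGTGGGAGCTGCTGGGC for miR396 (5288), AGGTCAAGAAATATGCCCAT for tasiARF (1410), TCTCTCTTTTATTACTATTC for miR529 (1406), TCATCTGTCTCTAGAGTGTT for miR156/miR157 (1056) and CTCTGTAAATACGGCAAAGG for miR7122 (873). miR156/miR157 and tasiARF had no called full site. Their full sites were searched only with abundant tags whose 5′ ends lie 1 nt from those of the family sequences that these short matches pair with. A full site at these slice positions was therefore not tested. The short matches alone are not evidence of a slice, and the missing call is not evidence against one. Full sites of miR529, which had 0 reads, and of miR7122 were not searched.

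Downstream of slices by miR482/miR2118, miR828 and miR3954, 21-nt siRNAs often lay in steps of 21 nt that began at the slice, again in a comparison added after the data were seen. Of 97 called sites of miR482/miR2118, miR828 and miR3954, 43 had enough sequence and reads, and the slice register held more reads than any other of the 21 registers at 25 of them (58.1%). Chance gives 4.76%; the upper binomial bound was 7 sites. The slice register led at 21 of 37 sites of miR482/miR2118, 3 of 3 of miR828 and 1 of 3 of miR3954. In the median site 35.9% of the siRNA reads were in register, and at 15 sites at least 50% were. Another register led at 18 sites, most often the one 1 nt further (7 sites). For miR390 and miR858, also on the trigger list, the slice register led at 0 of 2 and 0 of 1 measured sites. It held 5.16% and 9.15% of the reads at the miR390 sites and 0.749% at the miR858 site. Only sequence downstream of a slice was read, so siRNAs made upstream of one could not be seen. These values therefore do not decide whether miR390 or miR858 slices start phased siRNAs. Over all families with measured sites it led at 25 of 46. At the miR482/miR2118 slice before GCTGGAAAGAAAAATAAGGT, 97.3% of 228371 siRNA reads were in register, and the leading tag of the fruitlet library was the second siRNA of this register. Without the most abundant siRNA, 512 of 6655 reads at this site were in register and another register led. Another site, with the slice before GTTGGAAAGCAAAAAGAAAA, had 93.3% of 296179 reads in register, of which the siRNA at position 43, counted from 1 at the slice, gave 267650. Without that siRNA 8721 of 28529 reads were in register and another register led. At the miR828 slice before TTGAGCAAGATGTAATGAGC, 96.3% of 186910 reads were in register, led by the siRNA that begins at the slice (73159 reads) and the next one (52735 reads).

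**Figure D3:**
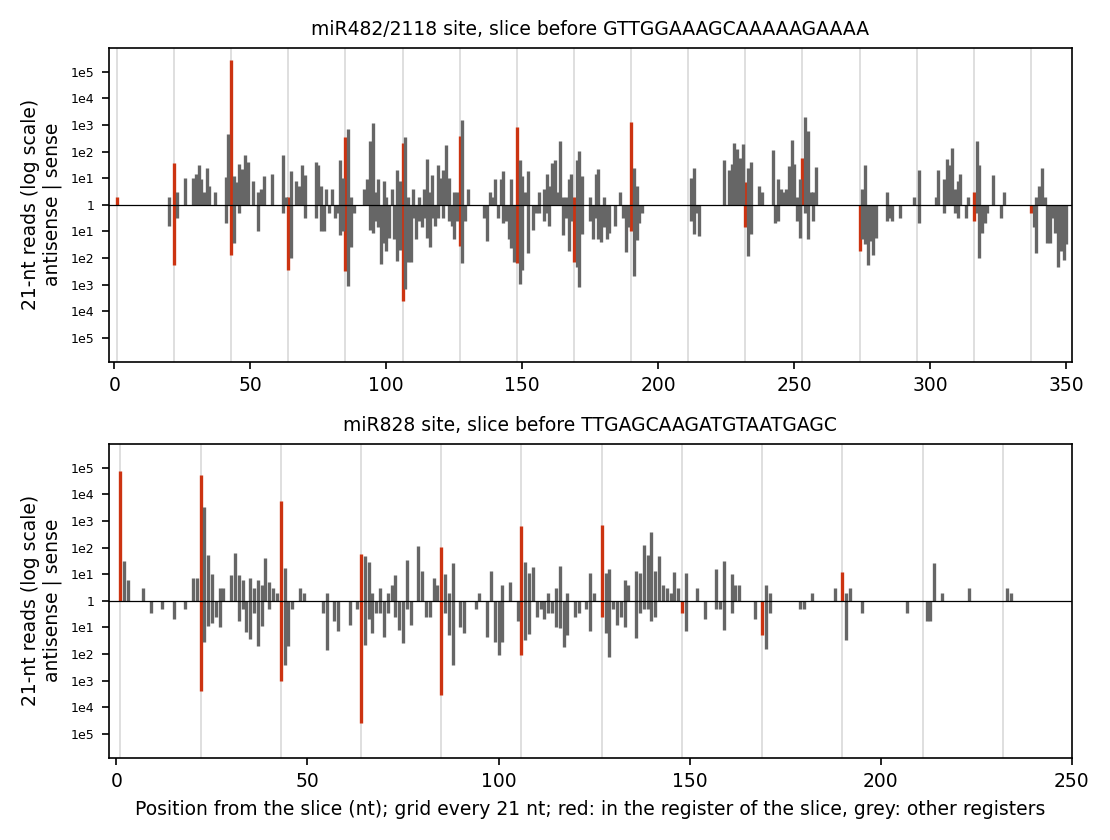
21-nt siRNA reads of all 6 libraries (y axis, log scale, sense up and antisense down) by position in nt from the slice (x axis) at a miR482/miR2118 site and a miR828 site. Red lines lie in the register of the slice and grey lines in other registers, and the red lines hold 93.3% and 96.3% of the reads; at the first site 267650 of 296179 reads come from 1 siRNA.

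Levels of siRNAs in the slice register were summed over all called sites of a family, including sites with too little sequence or too few reads for the comparison of registers. Those of miR482/miR2118 reached 20167 RPM in fruitlet (95% Poisson interval 20103 to 20231), 13276 in pedicel and 8699 in flower, with 6458 in stem, 6097 in leaf and 4598 in root. From the sites with enough sequence and reads alone, fruitlet had 15829 RPM, pedicel 9221, flower 7779, leaf 4233, stem 4225 and root 2596. Few tags carried the sums over all sites: GAAGAAGACTGCCATAACTGA had 8589 RPM in fruitlet and 2689 in pedicel, TAAGCATGGACGGATGAACAA, from a site with too little sequence, 3978 and 3855, and TGGAGTCATGAATTGTTGGAT 5439 in flower. Without the most abundant siRNA of each site, an alternative added after the data were seen, miR482/miR2118 siRNAs stood at 1871 RPM in fruitlet, 1543 in pedicel and 1298 in flower, with 677 to 879 in the other tissues. Moved by 10 nt, the same register held 83.9 to 306 RPM. Those of miR828 reached 4815 in leaf (4785 to 4845) and 220 in fruitlet (213 to 226), with 752 to 1314 in the other tissues, and at 2842 and 155 without those siRNAs. Those of miR3954 ranged from 32.5 in flower to 139 in root, where the moved register held 26.3, and from 7.51 to 88.0 in the same tissues at sites with enough sequence and reads.

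**Figure D4:**
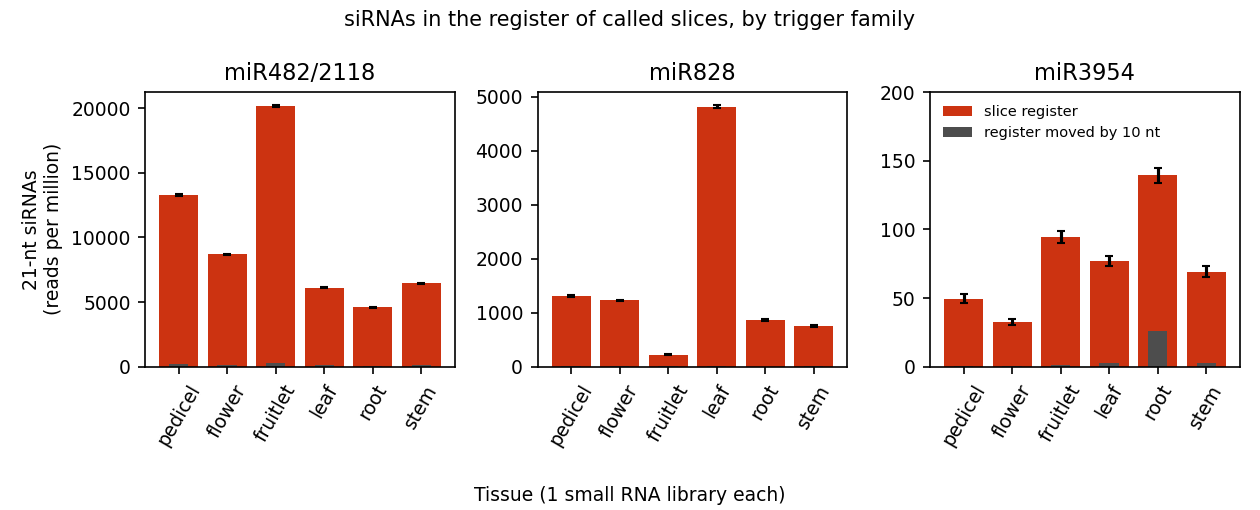
Levels of 21-nt siRNAs (y axis, RPM) in the register of slices by miR482/miR2118, miR828 and miR3954 in 6 tissues (x axis), 1 library each. Red bars carry 95% Poisson intervals, dark bars give the register moved by 10 nt, and the tallest bars are fruitlet at 20167 for miR482/miR2118, leaf at 4815 for miR828 and root at 139 for miR3954. Slices were searched only in fruitlet, pedicel and flower PARE tags.

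The flower libraries carried base forms that were rarer in the other tissues. Of the 82 called miR482/miR2118 sites, 10 had at least 100 reads in flower and at most 10 in fruitlet, and 11 the reverse, whereas between fruitlet and pedicel there were 1 and 0 such sites. The slice before ATTGGAAAGAAAAAATAGAC, for example, had 21567 reads in flower and 7 in fruitlet. Among PARE tags that were equal except at 1 base, 267 bases had opposite forms in fruitlet and flower, 247 in pedicel and flower, and 0 in fruitlet and pedicel, of 1975, 1686 and 924 bases with both forms. In the small RNA libraries, the flower form led at 14 of 18 covered bases in flower (77.8%), but at 1 of 22 in pedicel, 2 of 16 in fruitlet, 1 of 18 in leaf, 1 of 17 in root and 1 of 10 in stem. Reads of the flower form were 92.5% of such reads in flower small RNA, 17.5% in stem, 10.8% in leaf, 6.83% in root, 1.40% in fruitlet and 0.916% in pedicel, and 20.3% in the PARE mix. These comparisons were added after the data were seen, and every flower value above comes from libraries with these forms.

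**Figure D5:**
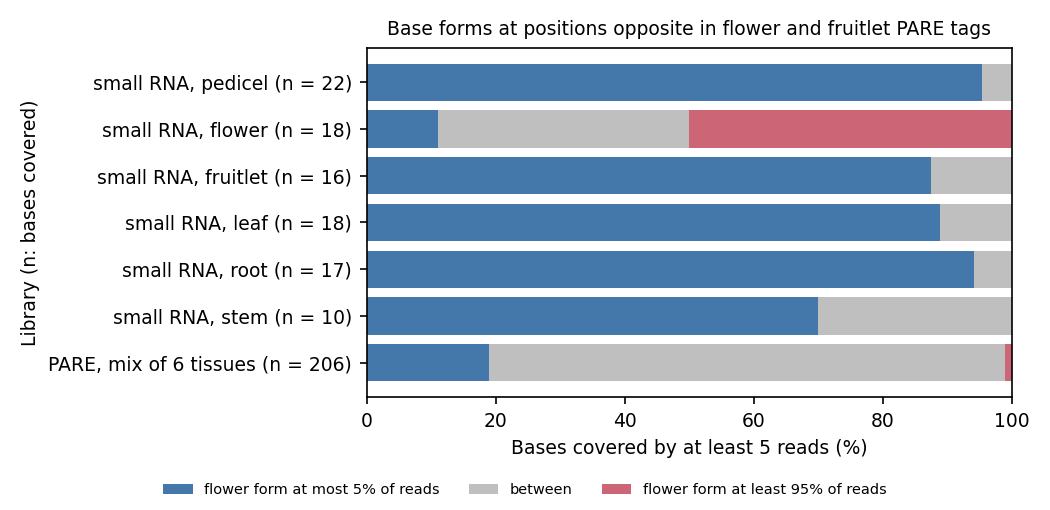
Percent of covered bases (x axis) at which the flower form had at most 5%, between, or at least 95% of reads, for 6 small RNA libraries and the PARE mix (y axis, with the number of bases covered). The flower library alone had bases at 95% or more among the small RNA libraries, 9 of 18.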

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

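The tests of arthropod and vertebrate markers were chosen after the first animal microRNAs had been seen.

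Sequences of animal microRNAs appeared in these plant libraries above the 3 reads that a count of 0 allows, which is why they are listed here. From the list fixed in advance, miR-1 reached 25.1 RPM in pedicel, with 9.53 in leaf and 0.530 in fruitlet, let-7a 7.46 in stem, with 4.22 to 6.37 in the other tissues, miR-184 4.01 in pedicel and miR-21 0.299 in root. From the list added later, miR-276a reached 2.69, miR-8 0.863, miR-71 0.710 and miR-9a 0.558 in pedicel, and miR-192 0.212 in fruitlet. The other 6 markers of the first list and 10 of the second had at most 3 reads in any library. Arthropods on the sampled trees are a candidate explanation, since 4 of the 8 added arthropod markers exceeded 3 reads in a library, all of them in pedicel. Among the insect markers of the first list, miR-184 had 79 reads in pedicel but bantam had 0. Vertebrate RNA had less support, with 1 of 7 added markers above 3 reads, at 4 reads, but stays open, since miR-21, a vertebrate microRNA of the first list, had 4 reads in pedicel, 6 in root and 4 in stem. Which animals, and whether let-7a with its even level came in during library preparation, was not tested, and no biological explanation within the tree was tested.

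Reads longer than 24 nt, outside the size classes compared, made up 5.10% of the pedicel library, above the other tissues, where the lowest share was 2.05% in fruitlet.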

How the results depend on the processing

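Alternatives that allow more substitutions or a 5′ shift, leave out libraries, remove structural RNA, use nearby overhangs or change the site and register settings were added after the data were seen. Of 52 alternative values for main results, 34 counted as the same by the rule set for each result, 17 as moved and 1 as reversed. For the length shares the rule was the widest counting interval, at most 0.0458 points, so small shifts in size counted as moved. Enriched and depleted families were 19 and 20 with a 2-fold threshold, which is laxer by construction, and depleted ones 6 with a minimum of 50 RPM; the other settings gave 7 to 10 and 7 to 13. The highest minus the lowest 24-nt share was 19.1 points, and 19.5 over distinct tags, 20.6 without listed families, 21.7 without tags seen once, 20.4 over 18 to 26 nt and 18.9 without structural RNA. For the 21-nt share it was 11.8, and 4.47, 12.1, 13.6, 10.3 and 11.9 in the same order. The 2-nt overhang lay above that of 3 to 10 nt in 1 of 18 pairs, in 0 with singletons, in 16 with tags of at least 10 reads and in 1 after thinning. That background needs fewer paired nt, so chance partners are easier in it. For miR390 and tasiARF r ran from 0.210 to 0.791 (exact permutation, adjusted p from 0.0639 to 0.658). The relation of miR482/miR2118 to duplexes reversed, to r = 0.510, when the excess over nearby overhangs was used; the cause was not tested. Signature families were 8 with no mismatch and 0 over distinct tags, against 4, and 4 to 6 otherwise; the cause was not tested for any of these shifts. Called sites ranged from 113 to 150 around 140, and sites led by the slice register were 18 of 43 without the top siRNA, 23 of 37 with 1000 reads and 22 of 33 with each sequence used once. No paired analysis was possible because each tissue had 1 library. The stricter score and unique mapping planned for phased loci were not run, as no genome was used. Depth limits miR828, with 81 reads in all.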

Other observations

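The search from PARE reads and the tests of base forms, of the register by chance and of trigger and siRNA levels were chosen only after the patterns they address had been seen.

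A search that started from the PARE reads, with no microRNA given, asked which slice-like ends are followed by siRNAs in register. Among 853122 tags, 61 starts met the rule, against 15 to 37 (mean 24.8) at 5 shifted registers. Of the 61, 26 were called slices, 20 of miR482/miR2118, 4 of miR3954 and 2 of miR828, against 0 to 2 at the shifted registers, and 35 were at no called site. Those 35 lay within the 15 to 37 starts of the shifted registers, so taken alone their number shows no excess. Some of them, however, begin as called slices do, with GTTGGAAAGA (miR482/miR2118), TTGAGCAAGA (miR828) or CTCTGTCCAA (miR3954). Whether these are slices that the site search missed was not tested. Some of the most abundant small RNAs lay in the register of a called slice. TAAGCATGGACGGATGAACAA, the second siRNA after the miR482/miR2118 slice before GTTGGAAAGCAAAATGGTTG, stood at 3978 RPM in fruitlet, 3855 in pedicel and 2117 in stem. That site had only 49 nt of sequence, so its register was not compared, and without this tag 155 of 807 reads were in register and another register led. TGGAGTCATGAATTGTTGGAT, the third after the slice before GTTGGAAAGCAAAAAGAAAA, stood at 5439 in flower, and there too the lead of the slice register rested on this tag.

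The siRNAs in the register of the slice were tested against 3 other origins. Chance registers are argued against, since the slice register led at 25 sites against a bound of 7. That bound takes the sites as independent. With each extended sequence used once, the slice register led at 22 of 33 sites against a bound of 6. A dominating tag per site as the whole cause is argued against, as the slice register led at 18 sites without the most abundant siRNA. Of the 25 sites, however, only 13 kept the lead and 12 lost it, while 5 others gained it. A single library is argued against as well, since the bound was exceeded in 6 of 6 libraries, from 15 of 37 sites in flower to 20 of 30 in root. Phased production from the sliced transcript is therefore a hypothesis these data suggest, found and tested on the same reads, and sites that share sequence also share siRNAs.

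Slices read in the flower library and not in the fruitlet library, or the other way, may come from trees of another genotype behind the flower libraries. The test found 267 bases with opposite forms in fruitlet and flower, against 0 in fruitlet and pedicel, which fits this explanation although the labels name 1 cultivar for all tissues. Near-identical gene copies used in different tissues stay open. Leaf, root and stem led with the flower form at no more than 10% of bases each, a result set beforehand to count against copies, but copies active mainly in flower would also give it, and the flower form had 17.5% of such reads in stem and 10.8% in leaf. If the trees differ, every flower difference in the report joins tissue with genotype, and the 2 cannot be told apart here.

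Over the 6 tissues, higher trigger levels did not go with higher siRNA levels beyond chance. Trigger levels here follow the added matches, with at most 3 substitutions for miR482/miR2118 (180 RPM in fruitlet to 1388 in root) and a 5′ shift of 1 nt for miR828 and miR3954, so they are not the family levels of the report. The miR482/miR2118 level is mostly that of TTGCCAATTCCACCCATGCCGT, with 3 sites, and only 17.7% of the family tags' reads are TCTTTCCAACACCTCCCATACC, with 77 sites, so it says little on the tag behind most slices. Pearson's r was -0.701 for miR482/miR2118 (exact permutation p = 0.125, adjusted over 3 relations 0.260; rho -0.829, exact permutation p = 0.0583, adjusted 0.175), and -0.106 without root and fruitlet, on which it rests. It was 0.628 for miR828 (exact permutation p = 0.174, adjusted 0.260; rho 0.143, exact permutation p = 0.803, adjusted 0.803), and -0.250 without leaf and flower, and 0.187 for miR3954 (exact permutation p = 0.725, adjusted 0.725; rho 0.314, exact permutation p = 0.564, adjusted 0.803), and 0.159 without leaf and pedicel. With the level of the tag that had most called sites as the trigger level, r was -0.323 for miR482/miR2118 (exact permutation p = 0.551, adjusted 0.744; rho -0.429, exact permutation p = 0.419, adjusted 0.846), and -0.570 without leaf and pedicel, 0.754 for miR828 (exact permutation p = 0.165, adjusted 0.496; rho -0.0857, exact permutation p = 0.919, adjusted 0.919), and -0.971 without leaf and flower, on which it rests, and 0.170 for miR3954 (exact permutation p = 0.744, adjusted 0.744; rho 0.314, exact permutation p = 0.564, adjusted 0.846), and 0.0987 without leaf and pedicel. The hypothesis that the trigger level sets the siRNA level remains undecided with 6 libraries. The siRNA sums also come only from sites found in fruitlet, pedicel and flower PARE tags, so sites sliced mainly in other tissues can be missing. Reads of miR828 were 81 beside 21400 PARE reads at its leading slice, and tags with its core in any length had 1.23 times the reads of the family match, so the match did not hide many.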
